A study of Rattus norvegicus with 30 samples.

How the data were processed

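Kidney and lung RNA of Sprague-Dawley rats was measured on single-colour oligonucleotide expression arrays with biotin-labelled target. Each organ was sampled at 1 wk of age, at 5 wk of age on a normal diet, called control, and at 5 wk of age in rats whose diet lacked tryptophan from birth until 4 wk, called deficient, with 5 rats per group and 30 arrays in all. The series design text speaks of mice, while the title and the sample labels name the rat, and the samples were treated as rat. According to the labels, total RNA was extracted with TRIzol, cleaned on RNeasy columns, and 2 ug was used per array.

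The deposited values are linear signal intensity values that the authors computed with MAS5, per the submitters' processing notes, which state no version. Each array held 31099 probe sets, of which 57 were control probe sets. The trimmed mean signal, with 2% left out at each end, was 499.98 on every array, so the deposited values were already scaled to a common level. No further normalization was applied. The 31042 other probe sets were assigned to genes by the deposited annotation. A single gene was named for 20826 of them, several genes for 436 and none for 9780, and those without a gene were not tested. Signals were transformed as log2(signal + 16), and the probe set with the highest mean signal stood for its gene, which gave 14217 genes. A gene was tested in a tissue if it reached the array's 40th percentile on at least 5 arrays of that tissue. This kept 10911 genes in kidney, 10802 in lung and 10154 in both. No genomic positions were used.

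Linear models were fitted per tissue to 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The contrasts were 5 wk control minus 1 wk, called the age difference, and 5 wk deficient minus 5 wk control, called the diet difference. A further contrast was 5 wk deficient minus 1 wk. Differences between the tissues came from a fit to all 30 arrays with interaction terms. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, and errors of log2 differences are standard errors (SE) from the fit. Folds are ratios on the scale of signal + 16 and are given only where both group means, and most arrays of each group, were above the arrays' 40th percentile. Gene lists written before the data were examined covered growth regulation, cell division, matrix, metabolism, immune genes and cell types. The 38 lists held 536 genes, of which 392 were tested in kidney and 397 in lung. Lists with at least 3 tested genes were compared with all other genes by camera with its preset correlation of 0.01, by camera with an estimated correlation, and by fry, and adjusted over 138 tests. Errors of list means are SE over arrays unless stated otherwise.

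An age score was computed for each array. The genes were those that changed at least 2-fold with age in the other tissue, so that the scored arrays had no part in choosing them. Same-numbered kidney and lung arrays were correlated within groups, so the choice was not fully independent of the scored arrays. A score of 0 is the mean of the 1 wk rats and 1 the mean of the 5 wk controls of the scored tissue. Deficient and control scores were compared by an exact two-sided permutation test over all 252 assignments, whose smallest possible p is 0.00794.

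Genes named in the text follow a rule fixed before the data were examined. It takes the 6 genes that rose most and the 6 that fell most in each comparison among called genes whose groups did not overlap. It adds a panel of 16 growth genes, up to 4 members with the smallest adjusted p and up to 2 with the largest from each list described, 4 genes per direction for each difference between tissues, and 5 genes per direction shared by both tissues. No probe set was named Peg3 or E2f3, and Dlk1 was below the filter in kidney. The comparisons, the tests, the filter, the gene lists and the alternatives were chosen before the data were examined, except where stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

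The procedure was tested on simulated data built from the spread of arrays within groups, with 200 changed genes. In the diet comparison of kidney, 20% of genes changed by 0.25 log2 were called, 68% of those changed by 0.5, and 100% of those changed by 1. In lung the corresponding shares were 36%, 72% and 94%. Among genes called in the simulated comparisons, between 3.70% (diet by tissue) and 8.05% (deficient against 1 wk in kidney) were unchanged. Alternatives were pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, quantile normalization, centring each array on its median, the mean of a gene's probe sets, all probe sets separately, a trended and robust variance, array weights, only the 10 arrays compared, all 30 arrays in 1 fit, the replicate number as a block, and leaving out each array. Differences between tissues were also fitted with same-numbered kidney and lung as 1 animal. Alternatives for the age score were genes of the same tissue with the controls split between choosing and scoring, and all called genes. An alternative without 4 arrays rich in liver transcripts was chosen after the data were seen. No array was left out of the values reported.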

Results

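Expression was measured in kidney and lung of rats at 1 wk of age, at 5 wk on a normal diet (control), and at 5 wk in rats whose diet lacked tryptophan until 4 wk of age. Tryptophan is an essential amino acid, and its lack slows growth. Each group had 5 arrays, 1 per rat and organ, and the number of arrays limits the precision. The mean of the arrays' median signals was 186 in 1 wk kidney, 151 in 5 wk control kidney and 163.5 in deficient kidney. In lung it was 178, 178 and 182. Correlations between arrays of a group lay between 0.974 and 0.985. The labels do not state whether a kidney and a lung with the same number came from the same rat.

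The age comparison in kidney asks, in the words of the series' aim, how fast-growing young animals differ from more slowly growing older ones. Igf2, a fetal growth factor, fell 9.79-fold (log2 -3.29 ± 0.20, SE, n = 5 per group, as in all comparisons that follow). H19, an imprinted non-coding RNA, fell 22.8-fold (-4.51 ± 0.21), and the imprinted gene Mest fell 13.7-fold (-3.77 ± 0.15). Mki67, a marker of dividing cells, fell 2.95-fold (-1.56 ± 0.12). Ghr, the growth hormone receptor, rose 3.48-fold (1.80 ± 0.07).

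The genes with the largest rises on the log2 scale in kidney were enzymes and transporters. Dhrs7l1 rose from a mean signal of 4.17 ± 3.78 (SD) to 7784 ± 1286 (log2 8.60 ± 0.39, limma adjusted p = 4.46e-11), and its log2 difference was 10.78 with 1 added to the signals and 6.83 with 64 added. The 40th percentile of an array, the level of the filter, lay between 87.0 and 116, and for genes with a group mean below it the log2 difference depends on the 16 added and no fold is given. This holds for the glucuronosyltransferase Ugt2b35 (6.77 ± 0.56), the histamine methyltransferase Hnmt (6.54 ± 0.13) and the organic anion transporter Slco1a1 (6.16 ± 0.48), which rose. Ugt2b35 was at 7.40 without 1 wk kidney 3. The cytochrome P450 Cyp4a8 rose 59.0-fold (5.88 ± 0.25) and AKR1C3l1 50.1-fold (5.65 ± 0.14). The neurofilament genes Nefm (-5.08 ± 0.16) and Nefl (-4.85 ± 0.13), Fbn2, a fibrillin of elastic microfibrils (-4.94 ± 0.19), and Tcp11 (-4.06 ± 0.19) fell to means below that percentile. The liver product Afp fell from a mean signal of 5365 to 5.20 (-7.80 ± 0.34, or -9.79 with 1 added and -6.10 with 64 added) and the liver product Alb fell 24.7-fold (-4.63 ± 0.85), and their signals differed widely among the 1 wk kidneys, with Alb between 1423 and 17459.8. In all of these genes the 5 arrays of one age lay apart from the 5 of the other, as the naming rule required. Igf1 (0.10 ± 0.07, adjusted p = 0.177) and the cyclin gene Ccnd1 (0.04 ± 0.07, adjusted p = 0.589) did not pass. Igf1 passed as higher with quantile normalization (adjusted p = 0.0402), median centring (adjusted p = 0.00269) and the mean of probe sets (adjusted p = 0.0324).

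Of 15 imprinted growth genes measured in kidney, 13 fell with age, 1 rose and 1 did not pass, and 14 passed when adjusted over the list alone. Examples are Cdkn1c, a cell cycle inhibitor (-3.12 ± 0.11), and Ndn (-2.78 ± 0.11), while Phlda2 did not pass (0.15, adjusted p = 0.206). The list's mean difference was -1.82 ± 0.05 (camera adjusted p = 7.43e-04, adjusted p = 0.0980 with an estimated correlation). Of 22 mitosis genes 21 fell and 1 rose, and 22 passed when adjusted over the list alone, with Bub1 at -1.88 ± 0.17 (camera adjusted p = 3.06e-05, adjusted p = 0.385 with an estimated correlation). All 21 DNA replication genes fell, and 21 passed when adjusted over the list alone, with Mcm6 at -1.74 ± 0.11 and Mcm3 at -1.62 (camera adjusted p = 5.79e-06, adjusted p = 0.291 with an estimated correlation). Of 13 fetal growth regulators 12 fell, and 12 passed when adjusted over the list alone, such as Igf2bp2 (-2.28 ± 0.08), Igf2bp3 (-2.61 ± 0.15) and Hmga1 (-1.87), while Suz12 did not pass (-0.11, adjusted p = 0.168). That list was lower by camera (adjusted p = 5.81e-05, adjusted p = 0.0507 with an estimated correlation). The panel genes Plagl1 (-2.28 ± 0.14), Mycn (-1.75 ± 0.15), Ezh2 (-1.42 ± 0.09), Top2a (-1.67 ± 0.18) and Igf1r (-0.35 ± 0.07) also fell. The list of the growth hormone and IGF axis did not move one way, with 5 of 16 genes risen, such as Igfals (2.79 ± 0.35) and Igfbp3 (0.81), 3 fallen, such as Igfbp2 (-2.12), and 8 passing when adjusted over the list alone (mean 0.26, camera adjusted p = 0.306).

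Of 22 extracellular matrix genes 21 fell with age in kidney, and 21 passed when adjusted over the list alone, among them Mfap2 (-3.34 ± 0.12) and Fn1 (-1.60 ± 0.06), with a mean of -1.72 ± 0.03 (camera adjusted p = 1.18e-07, adjusted p = 0.0507 with an estimated correlation). All 11 smooth muscle and myofibroblast genes fell, and 11 passed when adjusted over the list alone, with Acta2 at -2.44 ± 0.12 (camera adjusted p = 7.05e-05, adjusted p = 0.0980 with an estimated correlation). All 18 proximal tubule genes rose, and 18 passed when adjusted over the list alone, such as the organic cation transporter Slc22a2 (2.62 ± 0.10) and the cystine transporter subunit Slc7a9 (1.26 ± 0.04). Their mean was 1.00 ± 0.04 (camera adjusted p = 9.63e-08, adjusted p = 0.134 with an estimated correlation). Of 17 distal nephron genes 10 rose and 2 fell, and 12 passed when adjusted over the list alone, with Egf at 2.20 ± 0.08 (camera adjusted p = 0.0136, adjusted p = 0.166 with an estimated correlation). All 7 podocyte genes fell, and 7 passed when adjusted over the list alone, with Wt1 at -2.32 ± 0.13 and Nphs1 at -1.47 ± 0.10 (camera adjusted p = 0.0106, adjusted p = 0.134 with an estimated correlation). Of 17 mitochondrial respiration genes 15 rose and none fell, and 15 passed when adjusted over the list alone, with Ndufs1 at 0.94 ± 0.05 (camera adjusted p = 4.0e-05, adjusted p = 0.312 with an estimated correlation).

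All 8 MHC class II genes rose with age in kidney, and 8 passed when adjusted over the list alone, including RT1-Da (2.96 ± 0.18) and Cd74 (2.65 ± 0.15), with a mean of 1.97 ± 0.22 (camera adjusted p = 8.62e-04, adjusted p = 0.189 with an estimated correlation). Of 11 interferon-response genes 7 rose and none fell, and 7 passed when adjusted over the list alone, among them Isg15 (2.55 ± 0.29) and Mx1 (2.26), with a mean of 1.23 ± 0.12 (camera adjusted p = 0.00381, adjusted p = 0.268 with an estimated correlation). Of 9 macrophage genes 7 rose, such as Lyz2 (2.31) and C1qa (1.32), 2 fell, 1 of them Mrc1 (-1.51), and 9 passed when adjusted over the list alone (camera adjusted p = 0.0451, adjusted p = 0.430 with an estimated correlation). Of 3 neutrophil genes S100a9 (-2.11) and Mmp9 (-2.02) fell and none rose, and 2 passed when adjusted over the list alone (camera adjusted p = 0.323). Of 3 B cell genes 1 rose and 1 fell, and 2 passed when adjusted over the list alone (median 0.12, mean -0.26, lower by camera with adjusted p = 0.935).

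In kidney 7848 of 10911 genes (71.9%) were called with age, of which 3383 rose and 4465 fell. A change of at least 2-fold was found in 698 genes that rose and 1012 that fell. The arrays of the 2 ages did not overlap in 59.4% of genes, against 0.794% by chance. The share that fell among called genes was 56.9%, and with each array centred on its median it was 43.8%. That centring moved the age kidney median of all genes from -0.07 to 0.08.

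The age comparison in lung puts the same question to a second organ. Igf2 fell 4.53-fold (-2.18 ± 0.22), H19 fell 9.24-fold (-3.21 ± 0.33) and Mki67 fell 2.26-fold (-1.18 ± 0.08). Pigr, the receptor that carries IgA across epithelia, rose 25.1-fold (4.65 ± 0.13), Ly6i 17.4-fold (4.12 ± 0.56, or 4.81 without 1 wk lung 1) and the monooxygenase Fmo2 13.5-fold (3.75 ± 0.18), while the matrix gene Tgfbi fell 9.51-fold (-3.25 ± 0.10). From 1 wk means below the 40th percentile the xenobiotic-metabolizing Cyp1a1 (7.12 ± 0.38), the chemokine Cxcl14 (5.50 ± 0.18) and the eosinophil chemokine Ccl11 (4.11 ± 0.30) rose. To 5 wk means below it Fbn2 (-5.11 ± 0.15), the collagen gene Col25a1 (-4.55 ± 0.14), Stfa3 (-4.28 ± 0.25), the retinoic acid binding protein gene Crabp1 (-3.65 ± 0.21) and Nptx1 (-3.29 ± 0.13) fell. The groups did not overlap in any of these genes, which the naming rule required of all but Igf2, H19 and Mki67.

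All 15 imprinted growth genes fell with age in lung, and 15 passed when adjusted over the list alone, such as Mest (-1.91 ± 0.11), Plagl1 (-1.76 ± 0.10) and Dlk1 (-1.01 ± 0.22), with a mean of -1.33 ± 0.07 (camera adjusted p = 2.27e-08, adjusted p = 0.0507 with an estimated correlation). Of 23 mitosis genes 22 fell and none rose, and 22 passed when adjusted over the list alone, with Top2a at -1.67 ± 0.10 (camera adjusted p = 1.65e-13, adjusted p = 0.102 with an estimated correlation). All 21 DNA replication genes fell, and 21 passed when adjusted over the list alone, with Mcm4 at -1.29 (camera adjusted p = 4.61e-11, adjusted p = 0.0941 with an estimated correlation). Of 12 fetal growth regulators 10 fell, and 10 passed when adjusted over the list alone, with Igf2bp3 at -2.17 ± 0.13 (camera adjusted p = 9.9e-05, adjusted p = 0.0484 with an estimated correlation). Of 22 matrix genes 19 fell and none rose, and 19 passed when adjusted over the list alone, with Mfap2 at -2.15 ± 0.07, while Dcn did not pass (-0.07, adjusted p = 0.654). The matrix list was lower by camera (adjusted p = 1.57e-07, adjusted p = 0.166 with an estimated correlation). Of 12 smooth muscle and myofibroblast genes 9 fell and none rose, with Acta2 at -1.06, and 9 passed when adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.296 with an estimated correlation). Igf1 (-0.30 ± 0.08), Igf1r (-0.89 ± 0.10), Ghr (-0.41 ± 0.10), Mycn (-0.93 ± 0.16) and Ezh2 (-1.09 ± 0.07) fell, and Ccnd1 did not pass (-0.04, adjusted p = 0.571). Of 15 genes of the growth hormone and IGF axis 9 fell and 1 rose, and 10 passed when adjusted over the list alone (mean -0.29, camera adjusted p = 0.0317, adjusted p = 0.173 with an estimated correlation).

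Of 11 interferon-response genes 10 rose with age in lung, and 10 passed when adjusted over the list alone, with Isg15 at 2.68 ± 0.18 and Usp18 at 2.60 ± 0.16, while Rsad2 did not pass (0.12, adjusted p = 0.593). Their mean was 1.59 ± 0.12 (camera adjusted p = 5.9e-06, adjusted p = 0.134 with an estimated correlation). All 7 T cell genes rose, and 7 passed when adjusted over the list alone, with Il7r at 1.44 (mean 1.18 ± 0.13, camera adjusted p = 0.00134, adjusted p = 0.218 with an estimated correlation). All 5 B cell genes rose, and 5 passed when adjusted over the list alone, with Pou2af1 at 1.74 and Cd79b at 1.12 (mean 1.28 ± 0.18, camera adjusted p = 0.0220, adjusted p = 0.218 with an estimated correlation). Of 8 MHC class II genes 7 rose, and 7 passed when adjusted over the list alone, with RT1-Da at 1.58 ± 0.13 (camera adjusted p = 3.99e-04, adjusted p = 0.134 with an estimated correlation). Of 9 alveolar type 1 genes 8 rose, and 8 passed when adjusted over the list alone, with the water channel Aqp5 at 2.06 ± 0.08 (camera adjusted p = 0.00239, adjusted p = 0.214 with an estimated correlation). Of 10 airway epithelial genes 7 rose, and 7 passed when adjusted over the list alone, with Bpifa1 at 3.70 ± 0.39, while Scgb1a1 did not pass (0.03, adjusted p = 0.730). The airway list was higher by camera (adjusted p = 0.00378, adjusted p = 0.166 with an estimated correlation).

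In lung 5975 of 10802 genes (55.3%) were called with age, of which 3073 rose and 2902 fell, and 496 rose and 337 fell at least 2-fold. The ages did not overlap in 41.2% of genes, against 0.794% by chance. Ly6i rested on a wide 1 wk group, in which replicate 1 had a log2 signal of 10.89 and the others 6.81 to 7.76.

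The diet comparison in kidney asks how an earlier period of inhibited growth, on a deficient diet that ended at 4 wk, changes expression at the same age. In deficient kidney Mki67 rose 2.23-fold (1.15 ± 0.12), Top2a rose 2.37-fold (1.24 ± 0.18) and Mest rose 2.70-fold (1.43 ± 0.15, adjusted p = 2.97e-05). H19 was also higher (1.03 ± 0.21, adjusted p = 3.15e-03), whereas Igf2 did not pass (0.52 ± 0.20, adjusted p = 0.0787, and adjusted p = 0.0336 with the replicate number as a block). Slco1a1 fell (-4.43 ± 0.48), and its signals in deficient kidneys ran from 43.7 to 559, with 3 of 5 below the 40th percentile of their arrays. Vwf, the von Willebrand factor, fell 3.23-fold (-1.69 ± 0.14, adjusted p = 5.96e-06) as the only 1 of 13 endothelial genes, of which 3 rose and 5 passed when adjusted over the list alone (camera adjusted p = 0.436).

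The transporter gene Slc22a13 rose 3.05-fold (1.61 ± 0.35) and Pclaf, a partner of PCNA, 2.67-fold (1.42 ± 0.15). Gtse1, a gene of the G2 and S phases (2.14 ± 0.31), and Pcp4 (1.46 ± 0.24) rose from control means below the 40th percentile. So did the fibrinogen gene Fgb, a liver product (1.43 ± 0.40, adjusted p = 0.0203, and adjusted p = 0.105 with all 30 arrays in 1 fit). Other liver transcripts were also higher in deficient kidneys 3 and 4, where the mean log2 signal of 21 liver genes was 7.20 and 6.96, against 6.21 to 6.49 in controls. Alb, looked at after its values were seen, had signals of 1817 and 1382 there, against 64.5 to 361 in controls, and did not pass with diet (1.47 ± 0.85, adjusted p = 0.242). Dhrs7l1 fell from a mean signal of 7784 to 38.0 ± 48.7 (SD), below the 40th percentile (log2 -7.55 ± 0.39, adjusted p = 7.04e-08, or -8.52 with 1 added to the signals and -6.36 with 64 added). The trefoil factor gene Tff3 fell 7.99-fold (-3.00 ± 0.24) and Gc, which encodes the vitamin D binding protein, 5.85-fold (-2.55 ± 0.59). Gtpbp4 fell 5.57-fold (-2.48 ± 0.24), and Urah, an enzyme of urate breakdown, fell to a mean below the 40th percentile (-2.34 ± 0.33). Alb aside, deficient and control arrays did not overlap in any of these genes, as the naming rule required. Mycn (0.75 ± 0.15) and Ezh2 (0.53 ± 0.09) rose and Ghr fell (-0.48 ± 0.07, adjusted p = 1.79e-04). Igf1 (-0.02 ± 0.07, adjusted p = 0.856), Igf2bp3 (0.09 ± 0.15) and Ccnd1 (0.04, adjusted p = 0.700) did not pass.

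Calls of 2 panel genes in the diet comparison of kidney depended on single arrays. Igf1r rose (0.24 ± 0.07, adjusted p = 0.0283), but not without control kidney 3 (0.22, adjusted p = 0.0656) or 5 (0.22, adjusted p = 0.0660) or without deficient kidney 1 (0.19, adjusted p = 0.0663) or 2 (0.21, adjusted p = 0.0715). Plagl1 did not pass (0.40 ± 0.14, adjusted p = 0.0592), but did without control kidney 4 (0.50, adjusted p = 0.0202) and without deficient kidney 1 (0.47, adjusted p = 0.0382) or 2 (0.48, adjusted p = 0.0331).

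Of 22 mitosis genes in kidney 21 rose in deficient rats, and 21 passed when adjusted over the list alone, such as Ccna2 (1.40 ± 0.17), with a mean of 0.89 ± 0.13 (camera adjusted p = 1.6e-14, adjusted p = 0.135 with an estimated correlation). Of 21 DNA replication genes 19 rose and none fell, and 20 passed when adjusted over the list alone, with Mcm5 at 1.19 ± 0.14 (mean 0.66 ± 0.10, camera adjusted p = 1.65e-13, adjusted p = 0.121 with an estimated correlation). Of 22 matrix genes 17 rose and none fell, and 18 passed when adjusted over the list alone, with Col3a1 at 0.63 ± 0.08, while Col4a2 did not pass (0.07, adjusted p = 0.693). The matrix list was higher by camera (mean 0.53 ± 0.06, adjusted p = 2.37e-09, adjusted p = 0.0507 with an estimated correlation). Of 11 smooth muscle and myofibroblast genes 5 rose, such as Acta2 (0.60 ± 0.12), 1 fell, Tgfbi (-0.34), and 6 passed when adjusted over the list alone, while the list did not pass (mean 0.24 ± 0.06, camera adjusted p = 0.0595). Of 13 fetal growth regulators 8 rose and none fell, and 10 passed when adjusted over the list alone, with Igf2bp2 at 0.77 ± 0.08 (camera adjusted p = 3.06e-05, adjusted p = 0.0507 with an estimated correlation). Of 15 imprinted growth genes 6 rose and 2 fell, and 14 passed when adjusted over the list alone, with Cdkn1c at 0.86 and Ndn at 0.71 (mean 0.42 ± 0.06, camera adjusted p = 0.0175, adjusted p = 0.176 with an estimated correlation). Of 16 genes of the growth hormone and IGF axis 1 rose and 2 fell, 1 of them Igfbp3 (-0.78 ± 0.11), and 3 passed when adjusted over the list alone (mean 0.02, lower by camera with adjusted p = 0.942).

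Of 8 MHC class II genes in kidney 4 fell in deficient rats and none rose, and 5 passed when adjusted over the list alone, with RT1-Da at -1.25 ± 0.18 and Cd74 at -0.94 ± 0.15 (mean -0.77 ± 0.23, camera adjusted p = 5.78e-05, adjusted p = 0.136 with an estimated correlation). Of 9 macrophage genes 3 fell, such as C1qa (-0.59), 1 rose, Mrc1 (0.72), and 6 passed when adjusted over the list alone. The macrophage list had a median of -0.43 and a mean of -0.14 ± 0.13 (camera adjusted p = 0.0407, adjusted p = 0.407 with an estimated correlation). Of 11 interferon-response genes 2 fell, 1 of them Mx1 (-0.72 ± 0.20, adjusted p = 0.0179), and 2 passed when adjusted over the list alone (mean -0.32 ± 0.12, camera adjusted p = 0.00776, adjusted p = 0.303 with an estimated correlation). Of 25 amino acid response genes 1 rose and 2 fell, and 3 passed when adjusted over the list alone, with Ddit4 at -0.84 ± 0.16 and Aars1 at -0.29 (camera adjusted p = 0.0281, adjusted p = 0.121 with an estimated correlation). Of 18 proximal tubule genes 3 fell, including Slc22a2 (-1.02 ± 0.10), 1 rose, Slc22a7 (0.70 ± 0.16), and 4 passed when adjusted over the list alone. The proximal tubule list as a whole did not pass (mean -0.03, camera adjusted p = 0.306). None of 17 mitochondrial respiration genes was called over all genes or when adjusted over the list alone (camera adjusted p = 0.674). In kidney 2371 of 10911 genes (21.7%) were called with diet, of which 1527 rose and 844 fell, and 63 rose and 58 fell at least 2-fold. The share that fell among called genes was 35.6%, and with each array centred on its median it was 55.7%. The groups did not overlap in 14.2% of genes, against 0.794% by chance.

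The diet comparison in lung asks the same of the second organ. Mki67 rose 1.66-fold (0.73 ± 0.08), Top2a 1.85-fold (0.89 ± 0.10), and H19 2.74-fold (1.45 ± 0.33, adjusted p = 0.0104). Isg15, an interferon-induced ubiquitin-like protein, fell 2.88-fold (-1.53 ± 0.18), and the B cell receptor component Cd79b fell (-1.10 ± 0.25). Igf2 did not pass (0.38 ± 0.22, adjusted p = 0.294). Igf1, the main circulating mediator of growth hormone, fell (-0.53 ± 0.08, adjusted p = 7.92e-04), while Ghr did not pass (-0.13 ± 0.10, adjusted p = 0.429).

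Pimreg, a mitotic gene, rose 3.55-fold in deficient lung (1.83 ± 0.14, adjusted p = 4.88e-06), the cyclin gene Ccne2 2.31-fold (1.21 ± 0.16), the spindle kinase gene Ttk 2.28-fold (1.19 ± 0.16) and the cadherin gene Cdh22 2.21-fold (1.14 ± 0.18). Fbn2 (1.33 ± 0.15) and Scgb1c1 (1.75 ± 0.37) rose from control means below the 40th percentile, but Scgb1c1 did not pass with all 30 arrays in 1 fit (adjusted p = 0.0600). Avil fell 3.11-fold (-1.64 ± 0.23), the transcription factor gene Cebpd 3.05-fold (-1.61 ± 0.19), the MHC class I gene RT1-A 3.04-fold (-1.61 ± 0.31) and the interferon-induced protease gene Usp18 2.99-fold (-1.58 ± 0.16). The groups did not overlap in any of these genes, as the naming rule required. Plagl1 (0.74 ± 0.10), Mycn (0.96 ± 0.16), Ezh2 (0.54 ± 0.07), Igf1r (0.38 ± 0.10) and Igf2bp3 (0.81 ± 0.13) rose, and Ccnd1 did not pass (0.16 ± 0.06, adjusted p = 0.0925).

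Other calls in the diet comparison of lung depended on single arrays. RT1-T24-3 fell 3.22-fold (-1.69 ± 0.47, adjusted p = 0.0292), but not without control lung 1 (adjusted p = 0.0505), 3 (adjusted p = 0.0552) or 4 (adjusted p = 0.0638), and it was at -1.08 (adjusted p = 0.00220) without deficient lung 5. Dlk1 rose (0.85 ± 0.22, adjusted p = 0.0209), but not without control lung 4 (0.76, adjusted p = 0.0575) or deficient lung 2 (0.73, adjusted p = 0.0567) or 3 (0.74, adjusted p = 0.0572). Mest rose (0.39 ± 0.11, adjusted p = 0.0345), but not when any of control lungs 1, 3, 4 and 5 or deficient lungs 1, 2, 3 and 4 was left out (adjusted p between 0.0556 and 0.0720).

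Of 23 mitosis genes in lung 22 rose in deficient rats, and 22 passed when adjusted over the list alone, with Cdk1 at 0.86 ± 0.06 (mean 0.74 ± 0.06, camera adjusted p = 2.27e-27, adjusted p = 0.0507 with an estimated correlation). Of 21 DNA replication genes 18 rose, and 21 passed when adjusted over the list alone, with Tk1 at 0.79 ± 0.09, while Mcm3 did not pass over all genes (0.24, adjusted p = 0.150). The replication list was higher by camera (adjusted p = 1.13e-14, adjusted p = 0.0507 with an estimated correlation). Of 12 fetal growth regulators 8 rose and 1 fell, and 10 passed when adjusted over the list alone, with E2f8 at 0.85 (mean 0.43 ± 0.03, camera adjusted p = 9.06e-07, adjusted p = 0.0152 with an estimated correlation). Of 15 imprinted growth genes 9 rose and 1 fell, and 13 passed when adjusted over the list alone, with Slc38a4 at 0.65 (mean 0.49 ± 0.06, camera adjusted p = 1.1e-06, adjusted p = 0.0668 with an estimated correlation). Of 22 matrix genes 8 rose and none fell, and 10 passed when adjusted over the list alone, with Mfap2 at 0.82 ± 0.07 and Tnc at 0.58 (camera adjusted p = 6.02e-08, adjusted p = 0.166 with an estimated correlation). Of 12 smooth muscle and myofibroblast genes 1 rose, Tgfbi (0.52), and 1 passed when adjusted over the list alone (median -0.0038, mean 0.02, camera adjusted p = 0.942). Of 15 genes of the growth hormone and IGF axis 3 rose and 1 fell, and 4 passed when adjusted over the list alone (camera adjusted p = 0.224).

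Of 11 interferon-response genes in lung 10 fell in deficient rats, and 10 passed when adjusted over the list alone, with Mx2 at -1.16 ± 0.15 and Ifit2 at -0.95 ± 0.12 (mean -0.99 ± 0.13, camera adjusted p = 1.24e-12, adjusted p = 0.0507 with an estimated correlation). Of 7 T cell genes 6 fell, and 7 passed when adjusted over the list alone, with Lck at -0.63 ± 0.13 and Il7r at -0.68 ± 0.16 (mean -0.64 ± 0.15, camera adjusted p = 1.61e-05, adjusted p = 0.134 with an estimated correlation). Of 5 B cell genes 4 fell, and 4 passed when adjusted over the list alone, with Ms4a1 at -0.91 ± 0.20, while Cd22 did not pass (-0.19, adjusted p = 0.538). The B cell list was lower by camera (mean -0.86 ± 0.18, adjusted p = 7.43e-04, adjusted p = 0.115 with an estimated correlation). Of 9 macrophage genes 2 fell, 1 of them Mrc1 (-0.46 ± 0.07), none rose and 7 passed when adjusted over the list alone. The macrophage list had a median of -0.32 and a mean of -0.13 ± 0.08 (camera adjusted p = 0.00267, adjusted p = 0.1001 with an estimated correlation). Of 4 neutrophil genes Csf3r fell (-0.44), none rose and 2 passed when adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.206 with an estimated correlation). Of 8 MHC class II genes 3 fell, and 6 passed when adjusted over the list alone, with RT1-DMa at -0.48 ± 0.08 (camera adjusted p = 7.96e-04, adjusted p = 0.144 with an estimated correlation). Of 10 immediate early genes 3 fell, and 4 passed when adjusted over the list alone, with Zfp36 at -0.74 ± 0.13 (camera adjusted p = 3.14e-04, adjusted p = 0.166 with an estimated correlation). None of 12 alveolar type 2 genes, such as Sftpc (0.14, adjusted p = 0.364), and none of 9 alveolar type 1 genes, such as Aqp5 (-0.23, adjusted p = 0.0878), was called over all genes or when adjusted over the list alone. In lung 1274 of 10802 genes (11.8%) were called with diet, of which 672 rose and 602 fell, and 18 rose and 39 fell at least 2-fold. The groups did not overlap in 10.2% of genes, against 0.794% by chance. Over all comparisons camera with the preset correlation called 65 of 138 list tests, and the only 2 that held with an estimated correlation were the fetal growth regulators in lung, with age and with diet.

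**Figure D1:**
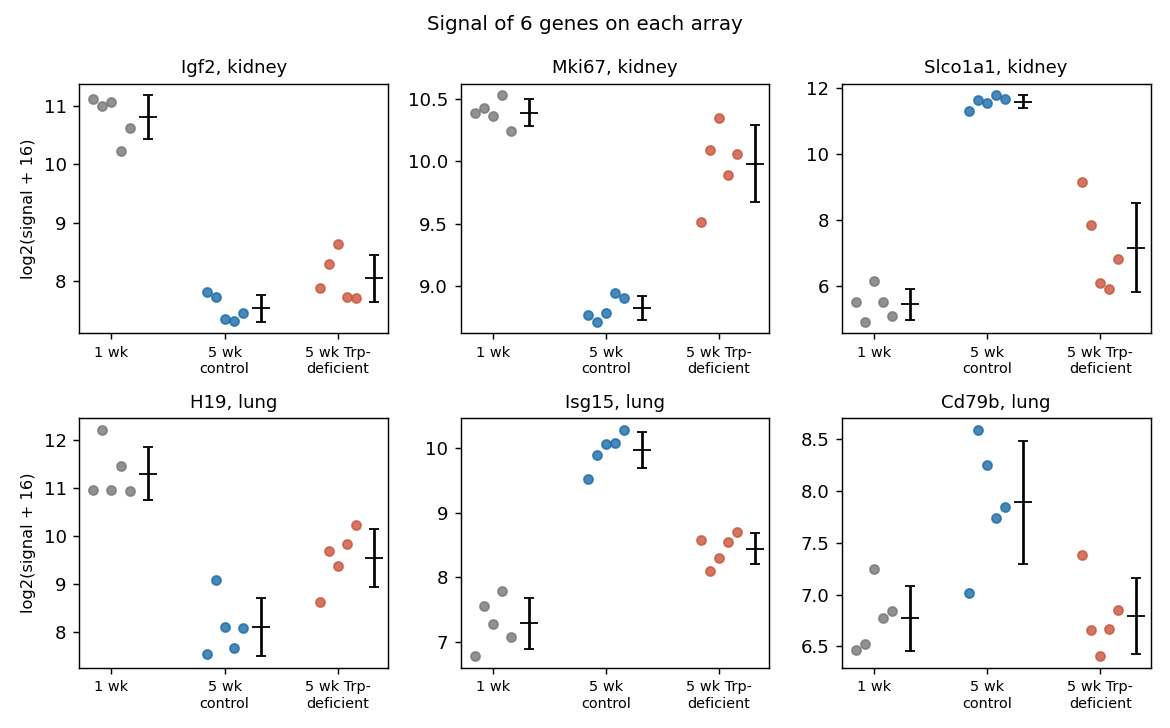
Log2(signal + 16) of 6 genes on each array, with the mean ± SD of each group of 5. Igf2 and Mki67 in kidney and H19 in lung are highest at 1 wk, and Slco1a1 in kidney and Isg15 and Cd79b in lung are lower in deficient rats than in 5 wk controls.

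**Figure D2:**
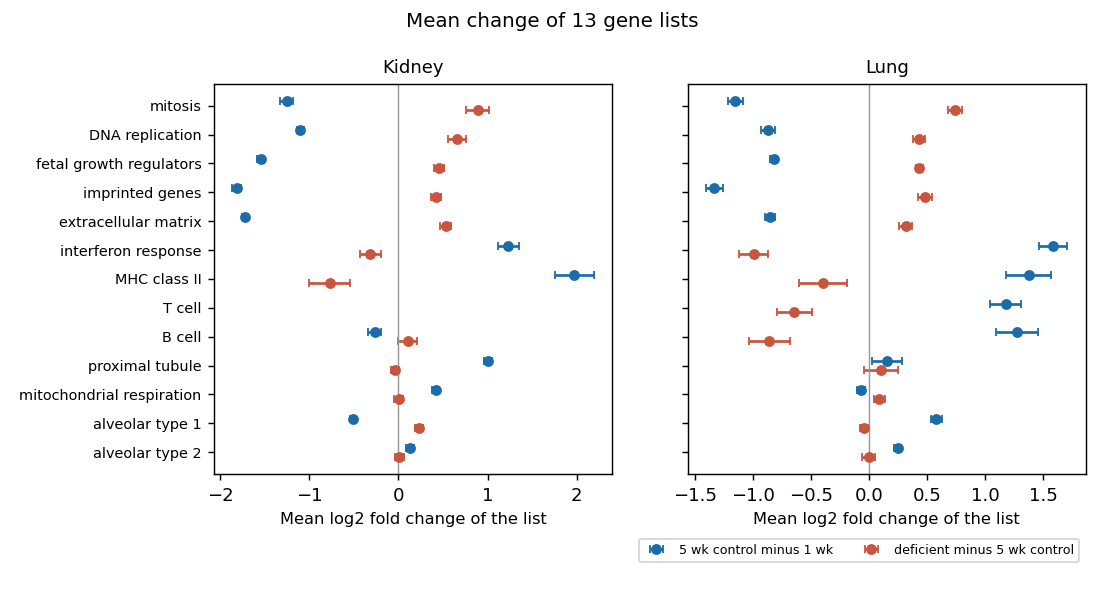
Mean log2 difference of 13 gene lists in kidney and lung, with SE over arrays, for 5 wk control minus 1 wk (blue) and deficient minus 5 wk control (red). The mitosis list is at -1.26 with age and 0.89 with diet in kidney, and at -1.15 and 0.74 in lung.

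Comparing deficient 5 wk rats directly with 1 wk rats asks how far the deficient organs were from the young state. In kidney 7161 genes were called, of which 3214 rose and 3947 fell. In lung 5348 genes were called, of which 2904 rose and 2444 fell. At least 2-fold changes numbered 1043 in kidney and 449 in lung.

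The age score places each deficient organ on a scale from the 1 wk mean (0) to the 5 wk control mean (1). Deficient kidneys had a score of 0.704 ± 0.068 (SD, n = 5), ranging from 0.605 to 0.778, over 343 genes that rose and 299 that fell in lung with age. Control kidneys ranged from 0.981 to 1.02. Deficient lungs scored 0.721 ± 0.030 (SD, n = 5), from 0.682 to 0.762, against 0.936 to 1.06 in control lungs, over 475 genes that rose and 923 that fell in kidney. All 5 deficient arrays lay below all controls in each organ, with an exact two-sided permutation p of 0.00794, the smallest possible. Genes that rise with age stood at 0.781 in kidney and 0.783 in lung, and genes that fall stood at 0.668 and 0.654.

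**Figure D3:**
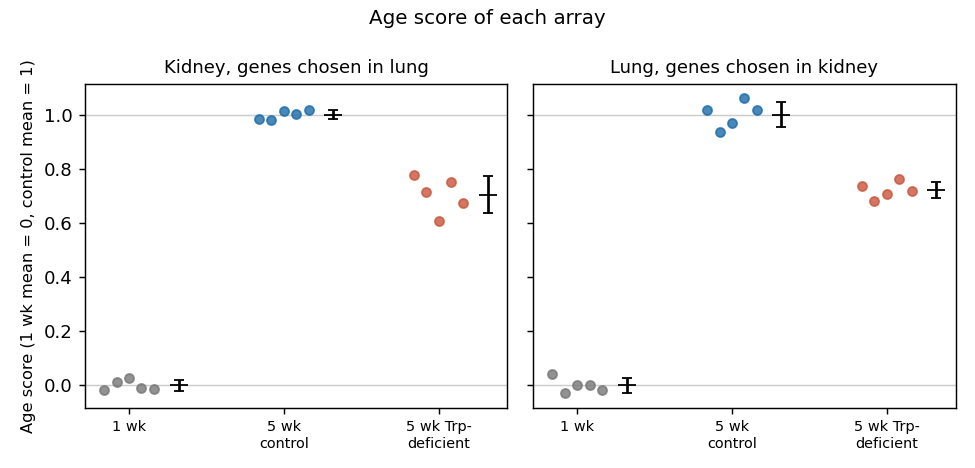
Age score of each array in kidney, with genes chosen in lung, and in lung, with genes chosen in kidney. Points are arrays and bars are the mean ± SD. All 5 deficient arrays lie below all 5 controls in each organ.

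Genes that fell with age, such as Mest and Mki67, tended to be higher in deficient rats, and genes that rose tended to be lower, such as Pigr. Among genes with an age change of at least 2-fold, 93.2% in kidney and 91.4% in lung had a diet difference of the opposite sign. Both differences use the same controls, which alone gave 66.6% in simulated data. That share is over all genes without any age change, so it is no baseline for genes changed at least 2-fold. With the controls split between the comparisons the shares were 89.3% and 86.5%. Of the genes called with diet in kidney 2166 were also called with age, 2107 of them in the opposite direction. In lung 1100 were called in both, 1039 of them in the opposite direction. Across genes, which are not independent replicates, the correlation of diet with age differences was -0.68 in kidney and -0.62 in lung. With the controls split it was -0.60 and -0.51, and then no array was shared, so sharing of controls cannot have produced it. Sharing of controls alone gave -0.50 and -0.50 in simulated data. Those data held no age or diet change, so these values are no baseline for the correlations found. The covariance was -0.163 in kidney, -0.155 with split controls and -0.008 in simulated data. In lung it was -0.084, -0.076 and -0.008.

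The organs can be compared for genes that moved alike. Pigr rose with age in kidney (4.70 ± 0.24) and lung (4.65 ± 0.13), as did Isg15 (2.55 ± 0.29 and 2.68 ± 0.18), the glutathione transferase gene Gsta1 (3.34 ± 0.10 and 2.12 ± 0.13) and the MHC class II gene RT1-Db1 (3.06 ± 0.20 and 2.06 ± 0.16). Fbn2 fell in kidney (-4.94 ± 0.19) and lung (-5.11 ± 0.15), as did the protease gene Adamts19 (-3.41 ± 0.19 and -2.72 ± 0.12), Cnih2 (-2.53 ± 0.22 and -2.43 ± 0.30), Wnt11 (-3.33 ± 0.15 and -2.37 ± 0.18) and Fndc1 (-2.33 ± 0.16 and -2.70 ± 0.11). With diet, Pigr fell in kidney (-1.10) and lung (-0.87) and Fbn2 rose in kidney (0.93) and lung (1.33). Among genes tested in both organs 1436 rose with age in both (796 expected from the single counts if the organs were independent) and 2093 fell in both (1191 expected). With diet 330 rose in both (89.9 expected) and 117 fell in both (36.5 expected). Across genes, which are not independent replicates, the organs' age differences correlated at r = 0.53 and their diet differences at r = 0.44. Same-numbered kidney and lung arrays were correlated within groups (0.173 to 0.310 in deficient rats), so part of the diet overlap can come from shared animals.

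Other genes changed differently in the organs, as tested by the interaction of age or diet with tissue. Tff3 rose with age in kidney (4.40) and not in lung (-0.09), a difference of 4.48 ± 0.27. The adrenergic receptor gene Adra2b rose in kidney (2.16) and fell in lung (-2.13), as did the transcription factor gene Etv1 (2.30 and -1.47). The reverse was found for Moxd1 (-3.82 and 1.08) and for the tight junction gene Cldn11 (-3.13 and 1.52). Ghr rose in kidney and fell in lung, a difference of 2.20 ± 0.12 (adjusted p = 1.98e-14). With diet, Gtse1 differed by 1.97 ± 0.36 and Cebpd by 1.62 ± 0.24, and Mest rose more in kidney than in lung (1.04 ± 0.20, adjusted p = 0.00130). Igf2bp3 differed by -0.71 ± 0.20 (adjusted p = 0.0294), while Igf2 (0.14, adjusted p = 0.855), H19 (-0.42, adjusted p = 0.610) and Mki67 (0.42, adjusted p = 0.0699) did not differ past the threshold. The age difference depended on tissue for 5523 of 10154 genes, 788 of them called in opposite directions. The diet difference did so for 777 genes, 38 of them in opposite directions. This fit treated the organs as unpaired, and with same-numbered organs as 1 animal 5796 genes were called with age and 1056 with diet.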

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

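The tests of RNA quality in both organs were chosen after the age scores had been seen. An earlier criterion, whether the actin 3'/5' ratio of deficient arrays lay between those of the age groups, was replaced before the adjusted scores were computed. By that criterion lung lies between (1.45, against 1.51 at 1 wk and 1.39 in controls) and kidney does not (2.06, against 1.73 and 1.99).

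Regrouping the arrays at random argues against chance for each count, though 1 in 100 is the smallest share that it can show. The other counts are not estimates of false calls, since mixed groups hold the real differences as spread, which lowers them. Each real count was compared with 100 splits, the real one included, of which 1 gave as large a count, namely the real one. For age in kidney the real count was 7848 and the highest other 3, and for diet in kidney 2371 and 84. For age in lung it was 5975 and 214, and for diet in lung 1274 and 8. For deficient against 1 wk it was 7161 and 4 in kidney and 5348 and 153 in lung. For genes shared by both organs with age it was 3529 and 0. The 0 follows from the few calls in regrouped kidneys, so it does not test whether the organs share more genes than by chance. For age by tissue it was 5523 and 1690, and for diet by tissue 777 and 35, with tissue labels exchanged within each condition after tissue means were removed.

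The age score of deficient organs lay below 1, at 0.704 in kidney and 0.721 in lung. The score is the mean log2 of genes that rise with age minus that of genes that fall, rescaled. A constant scaling factor of an array largely cancels in this difference and could hardly move the score. Scores of 0.713 and 0.716 after quantile normalization therefore argue only against unlike signal distributions of the arrays as the whole cause. A loss of RNA quality is argued against as the whole cause, since scores adjusted for the actin ratio were 0.708 ± 0.028 in kidney and 0.728 ± 0.026 in lung. Before the data were examined, fewer proximal tubule cells were predicted to raise the lists of the other kidney cell types by about the same amount. The podocyte list shifted by 0.241 ± 0.059, smooth muscle by 0.241 ± 0.056, distal nephron by 0.065 ± 0.026 and endothelium by -0.006 ± 0.037. The proximal tubule list, not part of that prediction, shifted by -0.034 ± 0.045. Scaling of arrays to a common level can hide a loss of cells in their own list, so such a loss stays open. Podocyte and endothelial genes differed in their shift by 0.247 ± 0.035. That gap cannot decide the question, since these lists were picked as the highest and lowest of those compared and each cell type can change by itself. A delay of maturation after the deficient diet, which the design names, may account for the scores. It stays a hypothesis, since it was found and tested on the same data. The organs were taken after that diet had ended. The scores therefore cannot separate an effect of the diet from one of the time after it.

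Interferon-response genes were lower in deficient lung by -0.99 ± 0.13. A single deviating control lung is argued against, since leaving out any 1 control lung changed the shift by a factor of at most 1.10, to between -1.08 and -0.90. Fewer leukocytes could account for it and stays open, since the interferon shift exceeded that of B cell genes by only -0.135 ± 0.196, although it exceeded that of T cell genes by -0.35 ± 0.12 and that of macrophage genes by -0.86 ± 0.14. A diet effect on interferon signalling stays open as well and was not tested separately.

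Liver transcripts were high in some 1 wk kidneys. The mean log2 signal of 21 liver genes was 9.30, 7.83, 10.8, 7.35 and 7.45 in 1 wk kidneys 1 to 5, and above 8 on only 2 further arrays, 1 wk lung 4 (8.52) and deficient lung 3 (9.07). Carry-over of liver tissue is a candidate explanation, since 66.7% of the other measured liver genes, 8 of 12, fell at least 2-fold with age in kidney, while Serpinc1 rose by 2.09. Kidney expression of Afp in young rats, where Afp was between 2645 and 11087 on all 5 arrays, stays open. Without the 4 arrays above 8, a choice made after the data were seen, Afp fell by 7.29 and Alb by 3.53 on the log2 scale.

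Single arrays lay far from the rest of their group in 26 of 315 groups of values, or 8.25%, where chance gives about 1 in 20. Values that follow are log2 signals, and the other arrays' range is in brackets. Mycn was 8.48 in 1 wk kidney 1 (8.08 to 8.16), 7.06 in control kidney 2 (6.13 to 6.36) and 8.05 in deficient lung 5 (8.39 to 8.49). Dhrs7l1 was 4.74 in 1 wk kidney 1 (4.11 to 4.27). Control kidney 2 had Cyp4a8 at 12.86 (13.13 to 13.23) and AKR1C3l1 at 12.82 (13.11 to 13.13). Deficient kidney 4 had Afp at 5.53 (4.16 to 4.48) and Tcp11 at 6.46 (5.25 to 5.53), and deficient kidney 5 had Gc at 6.60 (7.25 to 7.47). Ly6i was 10.89 in 1 wk lung 1 (6.81 to 7.76) and Ccl11 was 5.25 in 1 wk lung 3 (5.83 to 6.05). The T cell list was 6.80 in 1 wk lung 5 (7.13 to 7.16). Control lung 1 had Dlk1 at 7.67 (6.64 to 6.90) and Ccnd1 at 12.10 (12.29 to 12.36). Control lung 5 had Nptx1 at 5.81 (6.23 to 6.34) and the smooth muscle list at 9.84 (10.07 to 10.15), and control lung 4 had the endothelium list at 11.65 (11.74 to 11.78). Control lung 3 had an actin ratio of 1.53 (1.34 to 1.38, not a log2 value), the skeletal muscle list at 9.18 (8.53 to 8.68) and the cardiac muscle list at 11.24 (9.01 to 9.47). Deficient lung 4 had Stfa3 at 4.63 (4.13 to 4.28) and the skeletal muscle list at 10.81 (8.62 to 8.94). Deficient lung 5 had RT1-T24-3 at 6.99 (9.76 to 10.33), the alveolar type 1 list at 12.35 (12.49 to 12.51), the macrophage list at 10.12 (10.23 to 10.26) and the mast cell list at 9.10 (7.87 to 8.22).

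Among the many genes whose age or diet difference depended on tissue by the interaction test (5523 and 777), the 16 chosen by the naming rule are given as signed kidney minus lung log2 values. With age, Tff3 (4.48) and Akr1c13 (4.45) rose in kidney and stayed near 0 in lung (-0.09 and 0.15), and Adra2b (4.29) and Etv1 (3.77) rose in kidney and fell in lung. Moxd1 (-4.90), Cldn11 (-4.65) and the liver product Fgg (-4.45) were at -3.82, -3.13 and -2.72 in kidney and at 1.08, 1.52 and 1.73 in lung, and the value of Fgg was -3.67 without 1 wk kidney 3. Cyp1a1 (-4.58) rose in both organs, by 2.54 in kidney and 7.12 in lung. With diet, Gtse1 (1.97) was at 2.14 in kidney and 0.17 in lung, Cebpd (1.62) at 0.01 and -1.61, Pou2af1 (1.502) at 0.60 and -0.90, and Adgrv1 (1.46) at 1.06 and -0.40. Tff3 (-3.27) was at -3.00 in kidney and 0.28 in lung, Gtpbp4 (-2.75) at -2.48 and 0.27, Urah (-2.32) at -2.34 and -0.02, and Akr1c13 (-2.28) at -1.67 and 0.61.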

How the results depend on the processing

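The alternative without the 4 arrays richest in liver transcripts was chosen after the data were seen, and the others were fixed before. Of 294 counts under alternatives, 284 stayed within 1.5 times the count reported, including every count with 1 array left out. The exceptions came with all probe sets tested separately, where more features are tested, and with the list tests. With all probe sets the counts were 13692 for age in kidney (3167 of them at least 2-fold), 3623 for diet in kidney, 12328 for deficient against 1 wk in kidney, 9979 for age in lung (1373 at least 2-fold), 8912 for deficient against 1 wk in lung, 5878 for genes shared with age and 9087 for age by tissue. List tests called by camera numbered 65, by fry 86, and by camera with an estimated correlation 2, which is only in part a wider error by construction. The estimated correlation of many lists was above the preset 0.01, such as 0.573 for mitosis and 0.454 for DNA replication genes in kidney. It was -0.006 for the fetal growth regulators in lung, which held.

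The age score of deficient kidneys lay between 0.686 and 0.767 and that of deficient lungs between 0.709 and 0.776 under the alternatives run for it, always under 1. It was not recomputed with a trended and robust variance, array weights, only the 10 arrays compared or all 30 arrays in 1 fit. With the replicate number as a block the scores stayed at 0.704 and 0.721, but the sign-flip test over 5 pairs gave an exact permutation p of 0.0625, the smallest possible there.

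Named genes that were called kept their call and direction in 5769 of 5941 values under other settings and in 4562 of 4810 values with 1 array left out, and lost the call without changing direction in the rest. Uncalled named genes became called in the same direction in 130 of 4550 values under other settings and in 84 of 3570 with 1 array left out. They changed sign and stayed uncalled in 163 and 370 of these values. Direction changed with a call for 5 genes, none of them called in the values reported. With quantile normalization Ccnd1 was at -0.23 and Cs at -0.21 for age in kidney, and Slc34a2 at 0.11 for age in lung. With median centring Cpt2 was at 0.13 for age in kidney, and with the mean of probe sets Cav1 was at 0.27 for age in lung. The cause was not tested.

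Without the 4 arrays rich in liver transcripts 7368 genes were called for age and 2166 for diet in kidney, 5690 and 923 in lung, and the age scores were 0.711 and 0.729. Signal over background limits genes near the floor of the arrays, since log2(signal + 16) compresses their differences. Small changes were often missed in simulated data, where 22% of changes of 0.25 log2 were recovered for age in kidney and 28% in lung.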

Other observations

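The tests of kynurenine genes against a common share of the age change, and of the organs' likeness with arrays of different numbers, were chosen after the results were seen, and the other tests were fixed before.

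A first hypothesis was that kidney enzymes of tryptophan breakdown respond to tryptophan supply. The list of 12 kynurenine pathway genes was set before its values were seen, and 10 were measured in kidney. In deficient kidney 5 of them fell and none rose, namely Afmid (-0.73), Haao (-0.63), Kynu (-0.31), Qprt (-0.25) and Kyat1 (-0.16), and the list was lower by camera (p = 2.17e-06, and p = 0.00127 with an estimated correlation). All 10 rose with age in kidney, so that a general shift towards the younger state would also lower them. The mean beyond a common share of the age change was 0.07 ± 0.08. That error is an SE over the 10 genes, which are not independent replicates, and not over arrays. A response to tryptophan supply could therefore not be told apart from that shift and stays open. The deficient diet had ended before the organs were taken, so a response during that diet could be seen only if it lasted. In lung 5 genes were measured and none was called by limma. The criterion fixed earlier, a shift of the list, was met, and the criterion on the common share was added later because a shift of the list alone does not separate these readings.

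A second hypothesis was that the diet effect is 1 common delay, in which every gene is set back by the same share of its age change. The SD over genes of the diet effect around a common share was 0.406 in kidney (1710 genes, share -0.241) and 0.413 in lung (833 genes, share -0.266). The highest values simulated under 1 common delay were 0.254 and 0.258. This argues against an equal share for every gene as the whole account. A delay common in time was not tested, since genes that change at different times between the ages would then show unequal shares.

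Same-numbered kidney and lung arrays were more alike than others after group means were removed. Their correlation across genes, which are not independent replicates, was 0.119 to 0.312 among controls, 0.173 to 0.310 among deficient rats and 0.008 to 0.215 at 1 wk. The kidney's best match was the lung of the same number for 5 of 5 controls, 5 of 5 deficient rats and 4 of 5 at 1 wk. With same-numbered organs fitted as 1 animal (correlation 0.121), 5796 genes differed between tissues with age and 1056 with diet. With the replicate number as a block in the pairing of arrays, counts were 7791 and 2125 for age and diet in kidney and 5829 and 1072 in lung.

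Noise shared by same-numbered organs was tested as a cause of the likeness of diet differences in kidney and lung. Diet differences were computed from 3 kidneys per group and from the 2 lungs per group with other numbers, over 100 partitions. Their correlation across genes was 0.303 ± 0.037 (SD over partitions), against 0.373 ± 0.026 with lungs of the same numbers. Genes that rose in both organs averaged 57.4, with 7.68 expected, and exceeded the expected count in 100 of 100 partitions, and genes that fell averaged 7.04, with 1.89 expected, and exceeded it in 99. These correlations and counts argue against shared noise as the whole cause, while shared noise may add to the correlation found with all arrays. The partitions reuse the same arrays, so they are not independent trials and their SD is not a sampling error. The corresponding correlations of age differences were 0.497 ± 0.009 and 0.506 ± 0.008.

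Further lists were called with age by camera and not with an estimated correlation, and those given here are a part of them. Of 13 circadian clock genes 9 rose and 3 fell in kidney (Dbp at 1.54, adjusted p = 0.00776, adjusted p = 0.121 with an estimated correlation) and 9 rose and 2 fell in lung (Nr1d1 at 2.65, adjusted p = 0.0208, adjusted p = 0.189 with an estimated correlation). Of 9 macrophage genes 7 rose and 1 fell in lung (Cd68 at 1.39, adjusted p = 0.00178, adjusted p = 0.0980 with an estimated correlation), and of 6 mast cell genes 4 rose and none fell in lung (Tpsab1 at 2.79, adjusted p = 0.0175, adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 12 and 11 clock genes, 8 macrophage genes and 4 mast cell genes passed, in either direction. Of 14 ribosome biogenesis genes 10 fell with age in kidney and none rose (camera adjusted p = 0.0211, adjusted p = 0.166 with an estimated correlation). With diet, 2 of 7 immediate early genes fell in kidney and none rose (camera adjusted p = 0.0175, adjusted p = 0.307 with an estimated correlation). The erythroid list was higher in deficient lung (camera adjusted p = 0.0410, adjusted p = 0.469 with an estimated correlation), with no gene called over all genes. Marker lists of 1 organ were also called in the other. In lung all 5 podocyte genes rose with age (camera adjusted p = 0.0147) and 3 fell with diet (camera adjusted p = 0.00202). In kidney 6 of 7 alveolar type 1 genes fell with age (camera adjusted p = 0.0410). With diet 3 of the 7 rose (camera adjusted p = 0.0136). A called marker list therefore need not reflect the number of those cells.

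The median, mean and camera direction of a list differed in sign in several lists that did not pass. For diet in kidney, mitochondrial respiration had a median of 0.02 and a lower camera direction, the proximal tubule a median of 9.1e-04 and a mean of -0.03, and endothelium a median of 0.09 and a mean of -0.01. For diet in lung, alveolar type 2 genes had a median of 0.02 and a lower camera direction. Cardiac muscle genes in lung had a mean of 0.09 with a lower camera direction.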
